A study of Mus musculus with 6 samples.

How the data were processed

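RNA sequencing values of 6 libraries of mouse bone marrow-derived macrophages were used. Per the labels' protocols, the marrow of female C57BL/6N mice aged 8 weeks was cultured with 20 ng/mL M-CSF in medium free of phenol red with charcoal-stripped serum. The cells were plated on day 7 and given a compound for 1 h and LPS for 6 h. The dose unit in the labels is garbled; stocks of 1 mM diluted 1 to 1000 give 1 µM. Libraries of mRNA were sequenced on a HiSeq 2500, per the labels' protocols. Reads were aligned to mm9 with STAR and handled with HOMER, DESeq2 and edgeR, whose versions are not given, per the submitters' processing notes.

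The deposited tables hold 3 units. RPKM values (exon reads scaled for transcript length and for the library's total tags) were made by the authors with HOMER's analyzeRepeats over exons, condensed to 1 entry per gene, per the file headers; the column names say FPKM and the command says RPKM. A table of the authors holds log2 expression values of the 6 libraries, transformed by an unnamed method, and a log2 fold change that is positive where controls are higher although its header reads the other way, which was checked against the values. The same table holds the authors' p-value and adjusted p-value for 24505 genes. Replicates were not pooled. The strand setting of the counting is not given in the sources used here, so a gene and an antisense partner cannot be told apart.

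Groups were taken from the sample titles and the column headers: hydroxyestrogens (2OHE2, 4OHE1 and 2OHE1 as replicates 1, 2 and 3) and controls (EtOH, E2 and 16Epi as replicates 1, 2 and 3). The characteristics field for treatment gives the opposite groups and was not used, because the ethanol in the protocol is the vehicle. The groups, tests, gene lists, rule for named genes and a set of alternative settings were fixed before the data were examined. The design had named a negative binomial test on counts, with limma on log2 of the value plus 0.1 as the test should the tables hold no counts. They hold none, so limma was used.

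RPKM values times transcript length and library total gave whole reads: 100% of 1895 to 2634 values per library below 20 reads and in genes under 6000 nt were within 0.1 of a whole number. The recovered reads served for filters, depths and limma-voom. Genes with at least 10 reads in at least 3 libraries were tested, 11991 of 24016. The main test was limma's moderated test on log2(RPKM + 0.1) with a variance trend on expression, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 (4 residual degrees of freedom, median 9.4 in all). Standard errors and 95% intervals are limma's. For 1 value alone, an exact permutation test of 3 against 3 cannot give a p below 0.1. Each hydroxyestrogen was compared with the 3 controls, and with the other hydroxyestrogens, in a fit with 1 coefficient per compound and 1 for the controls (2 residual degrees of freedom, from the controls). The 3 controls were compared in a fit with the roles exchanged. In these 9 comparisons a lone library is assumed to vary like the other group. In simulated data of the main design, 60% of 2-fold and 83.2% of 4-fold changes were recovered, and 5.11% of calls were false (20 simulations). For a lone compound against controls these were 31.3%, 68.7% and 10.1%. The simulations gave all 6 libraries the same spread at a given expression. Such rates do not cover hydroxyestrogen libraries that scatter more than the controls, as they did in these data.

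The 30 gene lists held 583 genes; 2 were matched by an older name and 1 was not in the table. The 25 lists with at least 5 tested members were tested with camera (preset correlation 0.01) and Benjamini-Hochberg adjustment over the lists, and with camera with an estimated correlation and fry as alternatives. They covered inflammatory cytokines and mediators, chemokines, interferon-stimulated genes, feedback inhibitors, NRF2, HSF1, ATF4, LXR, p53, estrogen receptor and aryl hydrocarbon receptor targets, endoplasmic reticulum stress, mitochondrial chaperones, the respiratory chain, the tricarboxylic acid cycle, glycolysis, cholesterol synthesis, lysosome and autophagy, inflammasome and NADPH oxidase, antigen presentation, alternative activation, cell cycle, metallothioneins and markers of macrophages and 6 other cell types. Medians of lists per compound were set among 10000 random lists matched on expression in 20 bins.

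Genes were named by a rule: the 10 largest rises and the 10 largest falls past the threshold with no overlap between the groups and a mean log2 CPM of at least 1, up to 4 tested members of each list with the smallest p, 16 genes whatever their values, and the 3 largest changes each way per compound comparison (the 2 smallest p where none passed). It took 137 genes, of which those of most weight are printed. Other genes are said to have been chosen after their values were seen. Results of some genes are not reported here.

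The alternatives were limma-voom, log2(RPKM + 1), that with a mean RPKM of at least 1, no filter, a filter of 10 CPM (recovered reads scaled to the library total), a minimum change of 1.5-fold, the replicate number as a block, and leaving out each library. Those chosen after seeing the data were median-ratio scaling, the authors' log2 values, no variance trend, robust variance estimation, no features under 200 nt, genes with a mean of at least 1000 reads, a correction of length and GC content, log2(RPKM + 1) for compounds and lists, limma-voom for named genes, and an estimated correlation and median-ratio scaling for lists per compound. GC content came from GRCm38 annotation and was known for 99.2% of tested genes. Total tags per library numbered 16660201 to 19752320 and reads in genes 14734225 to 17326353. Counting error is small for most named genes at this depth; other error is measured only by the spread among the libraries. Software: R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.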

Results

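Bone marrow-derived macrophages, which are macrophages grown from mouse bone marrow with the growth factor M-CSF, were exposed for 1 h to an estrogen at 1 µM or to its ethanol vehicle. They were then stimulated for 6 h with 100 ng/mL lipopolysaccharide (LPS), the bacterial cell wall component sensed by TLR4, and their mRNA was sequenced. The 6 libraries formed 2 groups of 3. The hydroxyestrogen group held the catechol estrogens 2OHE2 (2-hydroxyestradiol, replicate 1), 4OHE1 (4-hydroxyestrone, replicate 2) and 2OHE1 (2-hydroxyestrone, replicate 3). The control group held the vehicle EtOH (replicate 1), estradiol, labelled E2 (replicate 2), and an estrogen labelled 16Epi (replicate 3). Each compound had 1 library, so the spread within a group held compound differences as well as culture and library error. The labels do not say whether the libraries came from separate animals or cultures, and p-values measure only the spread among these 6 libraries, which may be technical. All 6 cultures received LPS, so no value here shows an unstimulated level. A treatment field in the labels gives the opposite assignment, calling the EtOH library a hydroxyestrogen; the sample titles, the column headers of the deposited tables and the vehicle named in the protocol give the assignment used here.

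Reads in annotated genes numbered 16059673 for EtOH, 15013412 for E2, 14734225 for 16Epi, 16808895 for 2OHE2, 17326353 for 4OHE1 and 16424057 for 2OHE1. Genes with at least 1 read numbered 13787, 13859 and 13838 in the EtOH, E2 and 16Epi libraries, and 13554, 13210 and 13385 in the deeper 2OHE2, 4OHE1 and 2OHE1 libraries. Among 3436 genes with a mean of 20 to 200 reads, the variance between libraries of a group was 5.56, 5.10 and 4.98 times the Poisson variance for EtOH, E2 and 16Epi. It was 9.42, 11.96 and 7.77 times for 2OHE2, 4OHE1 and 2OHE1, so this scatter moved with the group. Among 3116 genes with a mean of at least 1000 reads, pairs of controls stood at 10.8 to 15.0 times the Poisson variance. Pairs of hydroxyestrogens stood at 29.2 to 71.7 times. The 4OHE1 library stood apart on the first principal component (30.6% of the variance), at 50.5 against -19.4 to -1.51 for the other 5. The 10 most abundant genes took 9.42% of its reads and 7.67% to 7.99% of those of the others.

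The first comparison asked how macrophages given a catechol estrogen before LPS differed from those given vehicle or another estrogen. The largest rise among the genes named by size was that of Esam, an adhesion molecule of cell junctions, at 2.80 ± 0.729 RPKM (SD, n = 3) against 0.515 ± 0.247 in controls (log2 difference 2.28 ± 0.36 SE, adjusted p = 0.0129). Esam had only 11 to 25 reads per control library, and 71 to 129 per hydroxyestrogen library. Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, rose 3.15-fold, from 21.1 ± 0.471 to 66.8 ± 4.65 RPKM (SD, n = 3 per group; log2 difference 1.66 ± 0.08 SE). Il1a, which encodes interleukin-1 alpha, fell by 1.46 ± 0.10 (SE) on the log2 scale, from 735 ± 44.6 to 269 ± 40.8 RPKM (SD, n = 3 per group). The coagulation initiator F3 (tissue factor) fell by 1.84 and Serpinb2, a plasminogen activator inhibitor, by 1.55. Of 11991 genes tested with limma, 225 passed a Benjamini-Hochberg adjusted p of 0.05, 153 higher and 72 lower with hydroxyestrogens, and all 225 had no overlap between the groups. Over all tested genes 2396 (20.0%) had no overlap, where chance gives 10% for 3 against 3. The authors' deposited table calls 594 genes at the same threshold, 341 higher and 253 lower. Of the 225 genes, 207 are among them in the same direction. Esam is not among the authors' calls, nor are Zfp874b and Scimp, which are named below. The count depended on the libraries and on the variance model: it was 127, 86 and 76 without control replicates 1, 2 and 3, and 12 when the prior variance was not allowed to vary with expression. It was also 94 among 16399 genes with no filter, where Il1b (adjusted p = 0.0687), Serpinb2 (0.0540) and Il12b (0.0540) were among the named genes whose calls were lost, 370 among genes at 10 CPM, 346 among genes with 1000 reads, 141 with a 1.5-fold minimum, 433 with limma-voom and 483 from the authors' log2 values.

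Gclc lies on chromosome 9 (77602342 to 77642296, plus strand, mm9) and Il1a on chromosome 2 (129125346 to 129135708, minus strand), and each value counts reads over a gene's annotated exons. The other large rises were Ednrb, the endothelin B receptor, by 1.85 on the log2 scale (44.3 ± 10.0 against 12.05 ± 1.35 RPKM, adjusted p = 0.000866), and Layn, a hyaluronan receptor, by 1.81. Dio2, a thyroid hormone deiodinase, rose by 1.77, Acss2, an acetyl-CoA synthetase, by 1.68, Slc40a1, the iron exporter ferroportin, by 1.496, and the cell cycle inhibitor Cdkn2b by 1.41. Acss2 overlaps Acss2os on the other strand (mean 1.52 RPKM), so part of its reads is uncertain. Zfp874b rose by 1.49. Mir671 also rose by 1.49, but it lies inside the exons of Chpf2 on the same strand and its reads cannot be told from those of Chpf2. Among the falls, Ch25h, which makes 25-hydroxycholesterol, fell by 1.22 (35.7 ± 4.25 against 83.3 ± 7.32 RPKM, adjusted p = 0.000675). Gm6377 fell by 1.74, Cish, an inhibitor of cytokine signalling, by 1.09, Scimp by 1.08 and Mmachc by 1.07. Gm14023 fell by 1.37; it overlaps Il1a on the other strand, and the strand setting of the counting is not given in the sources used here, so it is uncertain as a gene of its own. The call of Esam was lost without control replicate 3 (adjusted p = 0.0641), and that of Dio2 without control replicate 3 (0.0633) or hydroxyestrogen replicate 3 (0.0506). Those of Zfp874b, Gm6377, Scimp and Mmachc were lost in 4 to 6 of the 6 fits that left out 1 library (adjusted p from 0.0506 to 0.173), and that of Cish without any 1 of the 3 controls (0.0526 to 0.0735).

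**Figure D1:**
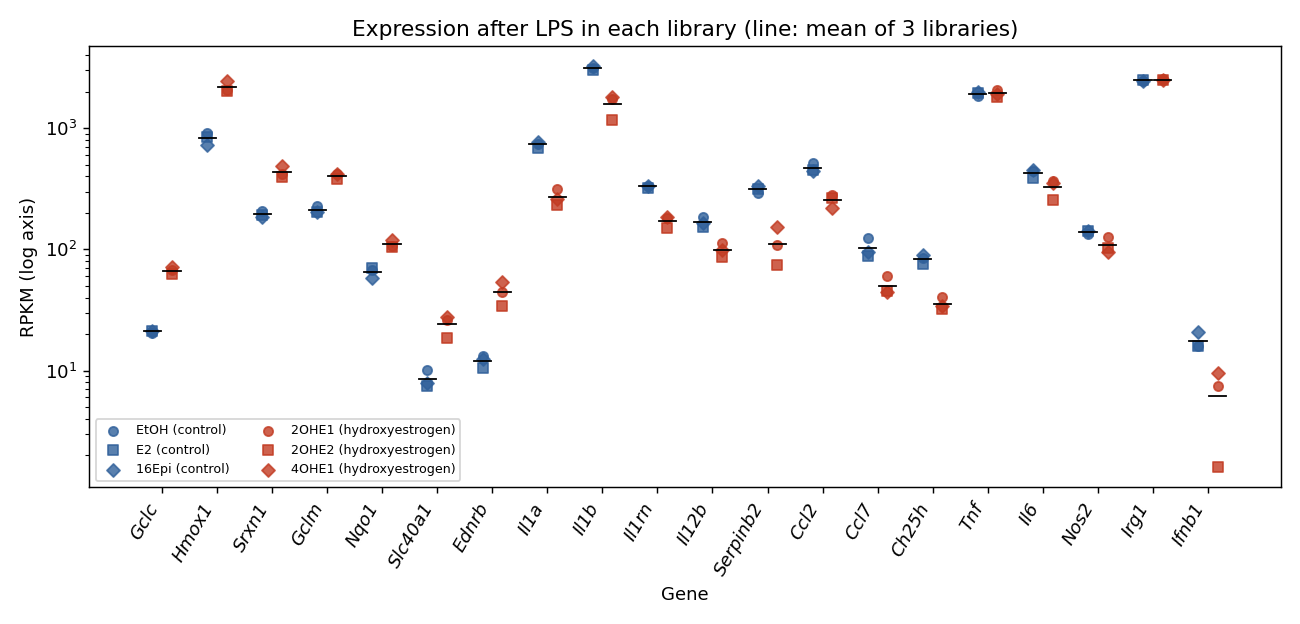
RPKM (log axis) of 20 named genes in each of the 6 libraries, with controls in blue, hydroxyestrogens in red and a black line at the mean of 3 libraries. Gclc sits at 66.8 RPKM with hydroxyestrogens and 21.1 in controls, Il1a at 269 and 735, while the Tnf means are 1944 and 1922.

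Targets of NRF2, the transcription factor that answers oxidants and electrophiles, rose as a group: 19 of 29 tested members passed the test, all higher, and 25 were higher when adjusted over the list alone. The list's median log2 difference was 0.59 and 28 members were positive. Besides Gclc, Hmox1 (heme oxygenase 1) rose 2.64-fold, from 826 ± 87.2 to 2183 ± 242 RPKM (SD, n = 3 per group; log2 difference 1.40 ± 0.10 SE, adjusted p = 0.000426). Cbr3, a carbonyl reductase, rose by 1.32 ± 0.10 (SE), Srxn1 (sulfiredoxin) by 1.15 ± 0.08, Gclm, the second subunit of the glutathione enzyme, by 0.93 ± 0.07, and the quinone reductase Nqo1 by 0.76 ± 0.09. These 6 kept their calls without any 1 of the 6 libraries, and the hydroxyestrogen libraries, where they were higher, also had the larger scatter (7.77 to 11.96 against 4.98 to 5.56 times the Poisson variance). Nfe2l2, which encodes NRF2, did not pass (log2 difference 0.17, adjusted p = 0.353). The list differed from other genes by camera with a preset correlation (adjusted p = 1.03e-37); with an estimated correlation the adjusted p was 0.0926, and no list passed that way.

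Inflammatory cytokines and mediators fell in part. Of 29 tested members, 6 were lower, 0 higher and 23 did not pass, and 17 were lower when adjusted over the list alone (camera adjusted p = 8.22e-13; adjusted p = 0.166 with an estimated correlation). The 6 were Il1a, F3, Il1b, Il12b, Tnfsf15 and Saa3. The list's median log2 difference was -0.40 and 3 of the 29 members were positive. Il1b, which encodes interleukin-1 beta, fell 2.03-fold, from 3148 ± 98.3 to 1579 ± 350 RPKM (SD, n = 3 per group; adjusted p = 0.00772), and Il12b, a subunit of interleukin-12, fell by 0.76 ± 0.11 (SE) on the log2 scale (adjusted p = 0.00847). The acute phase gene Saa3 fell by 0.64 and the TNF family member Tnfsf15 by 0.99, a call that was lost without control replicate 2 (adjusted p = 0.0501) or 3 (0.0578). Tnf and Irg1, LPS-induced genes among the list's few positive members, had values close to control. Tnf was at 1944 ± 126 against 1922 ± 65.4 RPKM (log2 difference 0.01, 95% interval -0.14 to 0.17, limma adjusted p = 0.957). Irg1, the itaconate-producing enzyme, was at 2513 ± 22.4 against 2476 ± 19.9 (0.02, interval -0.11 to 0.15, adjusted p = 0.915). The sign of Tnf turned without control replicate 1 (-0.01) or hydroxyestrogen replicate 3 (-0.03). The values of Il6 (log2 difference -0.40, adjusted p = 0.199) and Nos2 (-0.39, adjusted p = 0.128) did not pass, though both did with limma-voom (0.0362 and 0.0133), and Nos2 did without hydroxyestrogen replicate 3 (0.0175). The authors' own test also calls both lower (authors' adjusted p = 0.0305 for Il6 and 0.00282 for Nos2). Ifnb1, which encodes interferon beta, was at 6.19 ± 4.13 against 17.6 ± 2.89 RPKM and did not pass (adjusted p = 0.165); it did without hydroxyestrogen replicate 1, at a log2 difference of -1.04 (adjusted p = 0.0296), and with limma-voom (0.0140).

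Chemokines moved both ways, with 8 of 19 tested members lower and 1 higher (10 and 3 when adjusted over the list alone; camera adjusted p = 1.92e-05, downward; adjusted p = 0.238 with an estimated correlation). The monocyte attractants Ccl2, Ccl7 and Ccl12 fell by 0.88, 1.04 and 1.09 on the log2 scale, Ccl2 from 469 ± 40.0 to 256 ± 31.4 RPKM (SD, n = 3 per group; adjusted p = 0.00297). Ccl4 and Ccl9 fell by 0.54 and 0.53, and Cxcl10, Cxcl11 and Ccl22 were also lower. Cxcl3, a neutrophil attractant, rose by 0.74 (adjusted p = 0.0122). The calls of Ccl4 and Cxcl3 were lost without control replicate 2 (adjusted p = 0.0501 and 0.0640), and that of Cxcl3 also without control replicate 3 (0.0674). Feedback inhibitors of LPS signalling, whose products restrain the response, had 5 of 20 members lower and 1 higher, Dusp4 (10 and 1 when adjusted over the list alone; camera adjusted p = 2.37e-06, downward; adjusted p = 0.0926 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, fell by 0.95 ± 0.09 (SE), from 331 ± 7.63 to 173 ± 20.48 RPKM (SD, n = 3 per group; adjusted p = 0.00118). Socs1 fell by 0.62, Il10 by 0.51, Tnip3 by 0.50 and Socs3 by 0.36. The calls of Tnip3 and Socs3 were lost without control replicate 2 (adjusted p = 0.0660 and 0.106) or 3 (0.0727 and 0.103), that of Socs1 without any 1 control (0.0571 to 0.0760), and that of Il10 in 5 of the 6 fits that left out 1 library (0.0767 to 0.155). Those of Socs3 and Il10 were also lost with median-ratio scaling (0.0523 and 0.0609). The hydroxyestrogen libraries, where these groups were lower, also had the larger scatter. Over all genes with 20 to 200 reads it was 7.77 to 11.96 against 4.98 to 5.56 times the Poisson variance. Among genes with a mean of at least 1000 reads, pairs of hydroxyestrogens stood at 29.2 to 71.7 and pairs of controls at 10.8 to 15.0.

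The other lists that passed camera moved less. Glycolysis and HIF1 targets were shifted upward (median 0.20, camera adjusted p = 1.92e-05; 0.179 as an adjusted p with an estimated correlation), with 1 of 23 past the test, the glycolytic enzyme Gapdh at 0.45, and 11 higher and 1 lower when adjusted over the list alone. Targets of ATF4 had a median of 0.12 (camera adjusted p = 0.000119, and 0.238 with an estimated correlation). Of 28, 1 passed the test, the stress cytokine Gdf15, which rose by 1.25 ± 0.17 (SE). When adjusted over the list alone, 5 were higher and 1 lower. By compound the list's median was 0.01 with 2OHE1, 0.20 with 4OHE1 and 0.16 with 2OHE2. Atf4 itself did not pass limma's test (0.32, adjusted p = 0.192), though the authors' table calls it higher (adjusted p = 0.0141). Cholesterol synthesis genes had 0 of 20 past limma's test, 0 also when adjusted over the list alone and 7 with an unadjusted p under 0.05, with a median of 0.13 (camera adjusted p = 0.000377; adjusted p = 0.238 with an estimated correlation). Lysosome and autophagy genes had 2 of 21 higher, the autophagy genes Sqstm1 and Gabarapl1 (camera adjusted p = 0.00531; adjusted p = 0.238 with an estimated correlation). HSF1 targets and chaperones had 1 of 23 higher, the ubiquitin gene Ubb (camera adjusted p = 0.0134; adjusted p = 0.179 with an estimated correlation). Hsf1 (0.04), Hspa1a (0.17) and Hspa1b (0.10) did not pass; Hspa1a and Hspa1b are near-identical copies whose reads may be split between them. Without single libraries their signs turned: Hsf1 to -0.02 without control replicate 1 and -0.09 without hydroxyestrogen replicate 1, Hspa1a to -0.01 without control replicate 2, and Hspa1b to -0.03 without control replicate 1. Respiratory chain subunits had 1 of 74 higher, the ATP synthase gene Atp5g1 (median 0.04, camera adjusted p = 0.0197; adjusted p = 0.698 with an estimated correlation). Cell cycle genes had 0 of 25 past limma's test, 9 with an unadjusted p under 0.05, and a median of -0.11 (camera adjusted p = 0.0181, downward; adjusted p = 0.698 with an estimated correlation). The calls of Gapdh, Gabarapl1 and Ubb were lost without control replicate 2 (adjusted p = 0.109, 0.0553 and 0.0612) or 3 (0.125, 0.0631 and 0.0636), and that of Gapdh also without hydroxyestrogen replicate 2 (0.0723) or 3 (0.0759) and with median-ratio scaling (0.0651). The HSF1 list was lost without control replicate 2 (camera adjusted p = 0.0764), the cell cycle list without control replicate 3 (0.128) or hydroxyestrogen replicate 3 (0.174), and the respiratory chain list without control replicate 3 (0.123) or hydroxyestrogen replicate 2, where its direction turned (0.965).

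Camera did not separate 14 of the 25 lists it tested from other genes. Interferon-stimulated genes had a median of -0.05 with 1 of 40 past the test, Oasl1, higher (camera adjusted p = 0.256); without hydroxyestrogen replicate 3 the list passed downward (0.000139) and so did antigen presentation (0.0423). By compound its values went opposite ways, with a median of 0.10 with 2OHE1 (camera adjusted p = 0.00301, upward; adjusted p = 0.420 with an estimated correlation), -0.16 with 4OHE1 (0.0905) and -0.13 with 2OHE2 (camera adjusted p = 2.02e-07, downward; adjusted p = 0.254 with an estimated correlation). Macrophage identity genes had a median of -0.00 with 1 of 18 past the test, the myeloid transcription factor Cebpa, which rose by 0.92 ± 0.12 (SE; camera adjusted p = 0.926). Mitochondrial chaperones and proteases had 1 of 18 higher, Afg3l2, an inner membrane protease (camera adjusted p = 0.570). The inflammasome and NADPH oxidase list had a camera adjusted p of 0.871. LXR targets had 1 of 10 lower, the cholesterol exporter Abca1 (0.702), and their median (0.10) and mean (-0.07) differed in sign. The tricarboxylic acid cycle (adjusted p = 0.581), endoplasmic reticulum stress (0.499), alternative activation (0.816), estrogen receptor (0.570), aryl hydrocarbon receptor (0.867), p53 (0.843) and antigen presentation (0.183) lists had 0 members past limma's test, against 0, 2, 0, 0, 1, 3 and 5 with an unadjusted p under 0.05. The estrogen receptor gene Esr1 was near the floor, at 3 to 31 reads per library. Of markers of other cell types, neutrophil (5 tested, camera adjusted p = 0.360) and stromal genes (6 tested, 0.399) had 0 past limma's test and 0 and 1 with an unadjusted p under 0.05. The dendritic cell, lymphocyte, erythroid and mast cell lists had 2, 1, 0 and 1 members with enough reads, none past it, and could not be tested as sets, nor could the metallothionein list (4 tested, Mt1 higher). The calls of Oasl1 and Abca1 were each lost without control replicate 2 (adjusted p = 0.158 and 0.141) or 3 (0.176 and 0.173), that of Oasl1 also without hydroxyestrogen replicate 2 (0.102) or 3 (0.105) and with median-ratio scaling (0.0705), and that of Abca1 without control replicate 1 (0.129) or hydroxyestrogen replicate 1 (0.0667).

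Each hydroxyestrogen was also set against the 3 controls, with the spread taken from the controls. Among genes past the threshold and named by the rule, Ednrb, Layn and Gclc had the largest rises with 2OHE1 (log2 differences 1.90, 1.73 and 1.66), Esam, Ednrb and Layn with 4OHE1 (2.64, 2.16 and 1.98), and Acss2, Layn and Gclc with 2OHE2 (1.78, 1.71 and 1.55). Esam had values of 1.90 with 2OHE1 and 2.30 with 2OHE2, and Dio2 of 2.09 with 2OHE1, that did not pass (adjusted p = 0.168, 0.103 and 0.0781). Among the largest falls past the threshold were Vsig8 (-2.82) and F3 (-2.23) with 2OHE1, Nfatc2 (-3.41), Hdac9 (-2.49) and Smco4 (-2.49) with 4OHE1, and Ifnb1 (-3.37), Serpinb2 (-2.08) and Il1a (-1.66) with 2OHE2. Snhg9, a short RNA of 181 nt, had 5 reads with 2OHE1 and 81 to 120 elsewhere, and Nfatc2 had no read with 4OHE1, so its fitted value depends on the 0.1 RPKM added before the logarithm. Missing genes were counted among tested genes with a mean of at least 20 reads in the other 5 libraries, 11098 to 11135 per library. Of these, genes below 0.1 of their mean in the other 5 numbered 60 with 4OHE1, 42 of them without a read. The counts were 29 and 16 with 2OHE1, 17 and 8 with 2OHE2, and 7 to 13 and 3 to 5 in the controls. Hmox1 was higher by 1.33 with 2OHE1, 1.58 with 4OHE1 and 1.30 with 2OHE2 (SE 0.11 each; adjusted p = 0.0120, 0.00409 and 0.0109). Il1b was lower with all 3, at -0.85, -0.80 and -1.42 in the same order (SE 0.07 each; adjusted p = 0.00917, 0.00611 and 0.00138). The NRF2 target list had medians of 0.56, 0.68 and 0.52 and the cytokine list -0.28, -0.33 and -0.56, above 100% and 0% of 10000 random lists matched on expression; the 3 comparisons share their controls and are not independent. Camera passed both lists in all 3, but with an estimated correlation the adjusted p was 0.420, 0.401 and 0.254. Markers of other cell types moved in these libraries too: the neutrophil list had a median of -0.72 with 2OHE1 (camera adjusted p = 0.0215, downward; adjusted p = 0.420 with an estimated correlation), with Camp at -3.13 (adjusted p = 0.0293; 2 to 34 reads per library). S100a9, another neutrophil marker, was at -4.36 with 2OHE2 (1 to 62 reads), where the median of the neutrophil list was 0.03. The stromal marker Sparc was at -1.02 with 4OHE1, where the median of the stromal list was -0.64. Camera passed neither list in those libraries, so these are values of single members.

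The numbers of genes past the test were 65 for 2OHE1 (40 higher, 25 lower), 442 for 4OHE1 (169 higher, 273 lower) and 73 for 2OHE2 (36 higher, 37 lower). With median-ratio scaling they were 64 (41 higher, 23 lower), 421 (222 higher, 199 lower) and 83 (32 higher, 51 lower), so the share of higher genes went from 38.2% to 52.7% for 4OHE1 and from 49.3% to 38.6% for 2OHE2. Without control replicates 1, 2 and 3 the counts were 218, 8 and 62 for 2OHE1, 712, 70 and 250 for 4OHE1, and 199, 14 and 89 for 2OHE2. With trends on gene length and GC content removed they were 84, 259 and 66. Each of these fits assumes that the lone library varies like the controls, while the hydroxyestrogen libraries scattered more.

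**Figure D2:**
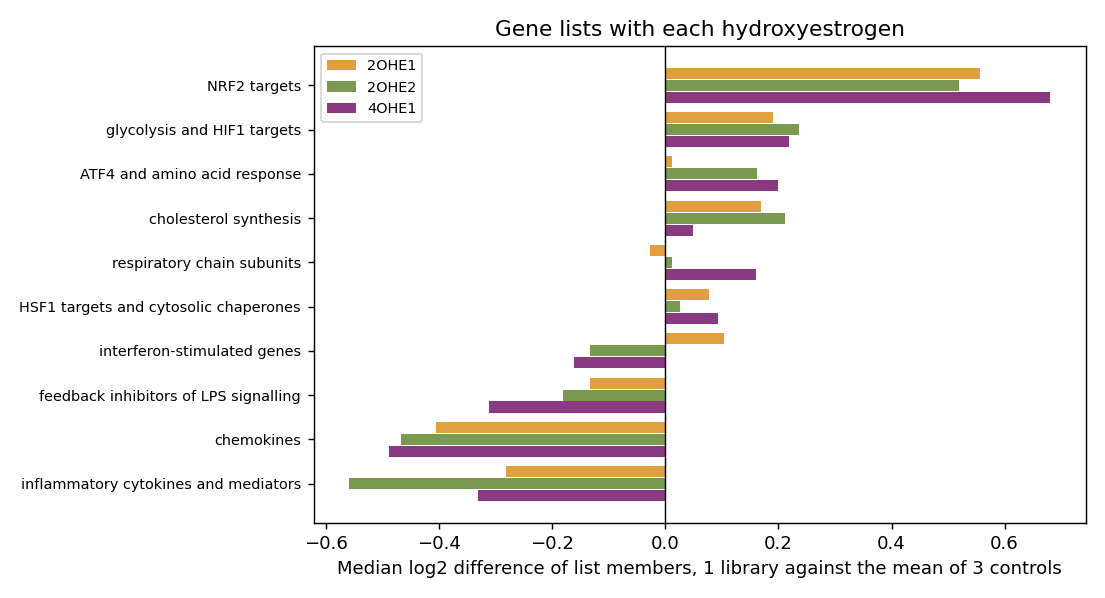
Median log2 difference of the members of 10 gene lists (horizontal axis) between each hydroxyestrogen library and the mean of the 3 controls, with 1 bar per compound and no error bar because each compound has 1 library. NRF2 targets lie at 0.56, 0.68 and 0.52 and cytokines at -0.28, -0.33 and -0.56 for 2OHE1, 4OHE1 and 2OHE2.

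The 3 catechol estrogens were then set side by side at the same dose and times. Each had 1 library and the spread came from the controls, which scattered less, so these tests compare libraries, and library error cannot be separated from the compound or its structure. 2OHE1 and 4OHE1 differ in the position of the added A-ring hydroxyl, and 2OHE1 and 2OHE2 in the ketone or hydroxyl at position 17. Between the libraries of compounds that differ in only 1 of these positions no protein-coding gene passed the test: the 5 calls of 4OHE1 against 2OHE1 and the 5 of 2OHE2 against 2OHE1 were all small or short RNAs under 200 nt with 0 to 120 reads. Between the 4OHE1 and 2OHE2 libraries 9 genes passed, 7 of them such short RNAs. The other 2 were Ifnb1, at 9.57 RPKM with 4OHE1 and 1.59 with 2OHE2 (145 and 23 reads; log2 difference 2.52 ± 0.25 SE, adjusted p = 0.0431), and Serpinb2, at 152 and 73.8 RPKM (log2 difference 1.04 ± 0.11 SE, adjusted p = 0.0431). With 2OHE1 these genes were at 7.41 and 109 RPKM, and in controls at 15.8 to 20.9 and 294 to 331. Without features under 200 nt limma called 0, 0 and 0 genes; with all features 1801, 1267 and 1892 had an unadjusted p under 0.05, and limma-voom called 269, 11 and 241. Without control replicates 1, 2 and 3 the counts were 45, 13 and 16 for 4OHE1 against 2OHE1, 37, 5 and 13 for 2OHE2 against 2OHE1, and 72, 9 and 23 for 4OHE1 against 2OHE2.

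For genes that did not pass, the intervals bound the difference only as far as the spread of the controls holds. The log2 difference of Hmox1 was 0.25 (95% interval -0.08 to 0.59) for 4OHE1 against 2OHE1 and -0.03 (-0.37 to 0.31) for 2OHE2 against 2OHE1, and 0.28 (-0.05 to 0.62) for 4OHE1 against 2OHE2. That of Gclc was 0.09 (-0.18 to 0.36), -0.11 (-0.38 to 0.16) and 0.20 (-0.07 to 0.47) in the same order. Il1b differed by 0.05 (-0.15 to 0.24) for 4OHE1 against 2OHE1, and its value with 2OHE2 was lower than with 2OHE1 by an amount whose interval excluded 0 before adjustment (-0.57, -0.77 to -0.38) but whose adjusted p was 0.196; its value with 4OHE1 was above that with 2OHE2 in the same way (0.62, 0.43 to 0.82, adjusted p = 0.0980). As sets, cytokines (median -0.29, camera adjusted p = 4.38e-06) and interferon-stimulated genes (median -0.21, camera adjusted p = 1.11e-15) had lower values in the 2OHE2 library than in the 2OHE1 library, calls between 2 lone libraries that were lost with an estimated correlation (adjusted p = 0.586). Cytokines also had higher values in the 4OHE1 library than in the 2OHE2 library (median 0.22, camera adjusted p = 0.000160; adjusted p = 0.793 with an estimated correlation). Interferon-stimulated genes also had lower values in the 4OHE1 library than in the 2OHE1 library (median -0.18, camera adjusted p = 0.000151; adjusted p = 0.607 with an estimated correlation). Fibroblast and stromal markers had lower values in the 2OHE2 library too (median -0.42, camera adjusted p = 0.0179; adjusted p = 0.767 with an estimated correlation). Respiratory chain subunits had higher values in the 4OHE1 library than in those of 2OHE1 (median 0.14, camera adjusted p = 3.82e-06; adjusted p = 0.607 with an estimated correlation) and 2OHE2 (0.13, camera adjusted p = 4.49e-08; adjusted p = 0.793 with an estimated correlation). That library also stood apart on the first principal component (50.5 against -19.4 to -1.51). Among tested genes with a mean of at least 20 reads elsewhere, it had 60 below 0.1 of their mean in the others, against 7 to 29. Of the 60 genes, 42 were without a read, against 3 to 16 in the other libraries. NRF2 targets also had higher values in the 4OHE1 library than in those of 2OHE1 (median 0.08, camera adjusted p = 0.00652; adjusted p = 0.607 with an estimated correlation) and 2OHE2 (0.13, camera adjusted p = 3.19e-05; adjusted p = 0.793 with an estimated correlation), and did not pass between 2OHE2 and 2OHE1 (median -0.04, camera adjusted p = 0.189).

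The last comparisons asked whether the 3 controls differed from each other, with the spread taken from the hydroxyestrogen libraries. No protein-coding gene passed. E2 against EtOH had 1 call, 16Epi against EtOH 2 and 16Epi against E2 2, all of them microRNA or small nucleolar RNA genes with 0 to 30 reads (Mir5121, Mir7072, Mir7045 and Snord99, which lie outside the rule for named genes and were picked for being the only calls). Limma-voom called 0, 0 and 0, and 162, 181 and 164 genes had an unadjusted p under 0.05. Without features under 200 nt limma also called 0, 0 and 0. Without hydroxyestrogen replicates 1, 2 and 3 the counts were 1, 3 and 0, then 4, 6 and 0, then 3, 7 and 0. For Hmox1 the difference between E2 and EtOH was -0.11 (95% interval -0.52 to 0.31), for Gclc 0.05 (-0.38 to 0.49), for Il1b -0.06 (-0.74 to 0.62) and for Tnf 0.07 (-0.30 to 0.43). Since the hydroxyestrogen libraries scattered more than the controls, these intervals are wide and the tests are conservative.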

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

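Of the tests of explanations here, those on distinct molecules were chosen after the result was seen; the fits with the length and GC correction, with median-ratio scaling and without short features were added after the data were seen, that with the length and GC correction before its own result was known.

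Between single libraries, limma called 5 genes for 4OHE1 against 2OHE1, 5 for 2OHE2 against 2OHE1 and 9 for 4OHE1 against 2OHE2, and 0, 0 and 0 without features under 200 nt, while with all features 1801, 1267 and 1892 genes had an unadjusted p under 0.05 and limma-voom called 269, 11 and 241. The spread came from the controls, which scattered less (4.98 to 5.56 against 7.77 to 11.96 times the Poisson variance), so these calls compare the libraries, and library error cannot be separated from the compound. Without control replicates 1, 2 and 3 the counts were 45, 13 and 16, then 37, 5 and 13, then 72, 9 and 23. Apart from short RNAs the calls were Ifnb1, which was higher with 4OHE1 than with 2OHE2 by 2.52 on the log2 scale, and Serpinb2, which was higher by 1.04. With 2OHE2 both had values below those of the controls (-3.37 and -2.08). Among the short RNAs, Snhg9 had 5 reads with 2OHE1 and 89 and 120 with the other 2 compounds, and Mir6963 had 0 with 4OHE1 against 17 and 18; Mir6963 was chosen after its values were seen.

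The main comparison was set beside the other splits of the 6 libraries. The real split gave 225 genes (127, 86 and 76 without control replicates 1, 2 and 3) and the highest of the others 2. So 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each other split mixes the groups, so any difference between the groups adds to its spread and lowers its count. The low counts of the other splits are therefore no support for the real one.

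4OHE1 had 442 genes past the threshold against the controls, 6.05 times the higher of the other 2 compounds, and 712, 70 and 250 without control replicates 1, 2 and 3; with no filter, where genes without variance are called by construction, the order turned (245 for 2OHE1, 266 for 4OHE1 and 307 for 2OHE2). The tables argue against sequencing depth (ratio 6.31 after every library was thinned to 14734225 reads in genes, with 54, 423 and 67 calls for 2OHE1, 4OHE1 and 2OHE2) and against trends on gene length and GC content as the whole cause, since the ratio was 3.08 after removing them (84, 259 and 66), although the 4OHE1 count fell from 453 to 259. A few genes taking more reads may contribute little: with median-ratio scaling the counts were 64, 421 and 83. Fewer distinct molecules would act mainly on rare transcripts. Among genes with a mean of at least 1000 reads the ratio was still 3.58 (251, 949 and 265). For the genes with fewer reads this explanation stays open. Among genes with a mean of 20 to 200 reads, pairs with 4OHE1 scattered 1.2 times as much as the pair without it. This was under the limit of 1.5 set for that test. But 60 genes sat below 0.1 of their mean elsewhere, 2.07 times the next library (29 with 2OHE1, 17 with 2OHE2, 7 to 13 in controls). These counts cover genes with a mean of at least 20 reads elsewhere. That first ratio averages in the other library of each pair and understates 1 noisy library (per library 11.96 for 4OHE1, 9.42 for 2OHE2 and 7.77 for 2OHE1), so it was read as undecided after its value was seen. Among genes with a mean of at least 1000 reads, 4OHE1 stood at 70.0 and 71.7 times the Poisson variance from 2OHE2 and 2OHE1. The pair of 2OHE2 and 2OHE1 stood at 29.2 and pairs of controls at 10.8 to 15.0. This scatter holds compound differences as well as library error, so the ratio of 3.58 cannot tell a noisy library from a stronger action. A stronger action of 4OHE1 also stays open, untested, because the compound has 1 library. The ratio of 6.05 itself depended on the controls, being lower without any 1 of them.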

How the results depend on the processing

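Of the alternatives below, median-ratio scaling, the authors' log2 values, no variance trend, robust variance, no short features, the minimum of 1000 reads, the length and GC correction, log2(RPKM + 1) for compounds, limma-voom for named genes and the estimated correlation per compound were added after the data were seen. The count of 225 genes for hydroxyestrogens against controls was 224 with log2(RPKM + 1), 255 with that and a mean RPKM of at least 1, 200 with median-ratio scaling, 252 with robust variance, 272 without short features and 241 with the length and GC correction. It was 433 with limma-voom (207 shared), 94 with no filter, 370 with 10 CPM, 141 with a 1.5-fold minimum, 483 from the authors' log2 values, 12 with no variance trend and 346 with a minimum of 1000 reads. Those with 94, 370 and 346 differ in the genes tested (16399, 8020 and 3116) and that with 141 drops small changes by construction; for the others the cause was not tested. Leaving out 1 library gave 76 to 198 genes.

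Against the controls, 2OHE1 (65 genes), 4OHE1 (442) and 2OHE2 (73) had 374, 1639 and 463 with limma-voom, 245, 266 and 307 with no filter, 107, 591 and 118 without short features, 251, 949 and 265 with a minimum of 1000 reads, and 84, 259 and 66 with the length and GC correction. Leaving out a control gave 8 to 218, 70 to 712 and 14 to 199. The comparisons of 4OHE1 with 2OHE1 (5), 2OHE2 with 2OHE1 (5) and 4OHE1 with 2OHE2 (9) had 269, 11 and 241 with limma-voom, 398, 467 and 458 with no filter, 4, 1 and 3 with log2(RPKM + 1), 0, 0 and 0 without short features, 0, 0 and 8 with a minimum of 1000 reads, and 9, 3 and 9 with the length and GC correction. Leaving out a control gave 13 to 45, 5 to 37 and 9 to 72. The comparisons of E2 with EtOH (1), 16Epi with EtOH (2) and 16Epi with E2 (2) had 0, 0 and 0 with limma-voom, 997, 1004 and 967 with no filter, 0, 1 and 0 with log2(RPKM + 1), 1, 3 and 5 with median-ratio scaling, 0, 0 and 0 without short features, and 0, 0 and 0 with a minimum of 1000 reads. Leaving out a hydroxyestrogen gave 0 to 3, 0 to 6 and 0 to 7. Unadjusted p under 0.05 in limma with all features was found for 1801, 1267, 1892, 162, 181 and 164 genes in these 6 comparisons. With no filter, genes without a read in the group that gives the spread have no variance, which makes calls by construction; elsewhere the cause was not tested.

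Of 25 lists, 11 passed camera; 0 did with an estimated correlation, a setting that also tests on the residual degrees of freedom of the libraries (4 here, 2 per compound) in place of the number of genes; feedback inhibitors lost their call at an estimated correlation of 0.00977, near the preset 0.01. There were 7 with fry, 11 with median-ratio scaling or log2(RPKM + 1), and 9 to 12 with 1 library left out. Fry passed NRF2 targets (adjusted p = 0.00433), feedback inhibitors (0.0072), cytokines (0.0279) and chemokines (0.0279). It also passed glycolysis (0.0279), HSF1 targets (0.0343) and lysosome and autophagy (0.046). Of the lists that passed camera, fry did not pass ATF4 targets (0.0937), cholesterol synthesis (0.0937), cell cycle (0.328) or the respiratory chain (0.496). Of 75 list tests per compound, 29 passed, 30 with median-ratio scaling and 0 with an estimated correlation. Of the 137 genes named by the rule 48 passed; 23 did with no filter, 49 with log2(RPKM + 1), 44 with median-ratio scaling, 61 with limma-voom and 31 to 49 with 1 library left out. Of 70 genes followed one by one, limma-voom ended 2 calls, median-ratio scaling 4, no filter 29, and leaving out control replicates 1, 2 and 3 ended 11, 20 and 22 and hydroxyestrogen replicates 1, 2 and 3 ended 6, 4 and 10. Signs turned for Tnf (-0.0127 without control replicate 1, -0.0335 without hydroxyestrogen replicate 3, up to 0.0599 otherwise), Hsf1 (-0.0172 without control replicate 1, -0.0900 without hydroxyestrogen replicate 1, up to 0.135), Hspa1a (-0.0148 without control replicate 2, up to 0.379) and Hspa1b (-0.0264 without control replicate 1, up to 0.229), none of them past the threshold; the cause was not tested. Median-ratio scaling moved the median of all genes by less than 0.1 in each comparison.

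With the replicate number as a block, 165 genes passed (155 shared), 40 of the named genes and 11 lists, and 9 of the 70 genes lost their calls. Libraries with the same number share only that number: their deviations from the group means correlated at -0.04, 0.07 and 0.04, and not each library correlated best with its own number. Size factors in a negative binomial model, its Wald test and its robust setting need counts and were not run; median-ratio scaling, limma-voom and robust variance stand in for them. Depth limits low genes most: Esr1 had 3 to 31 reads per library.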

Other observations

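The tests of overlapping reads and of gene families were chosen after the result was seen, and the genes in the first paragraph and in the pairs were chosen after their values were seen, so no theme is claimed for them.

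Ccr1, a receptor of several CC chemokines, fell by 0.84 on the log2 scale with hydroxyestrogens, from 22.3 ± 1.39 to 12.5 ± 1.17 RPKM (SD, n = 3 per group; limma adjusted p = 0.00683). The inhibitory Fc receptor Fcgr2b fell by 0.43 (adjusted p = 0.0129). Gss, glutathione synthetase, rose by 1.20, from 15.97 ± 1.51 to 37.2 ± 8.11 RPKM (SD, n = 3 per group; limma adjusted p = 0.00510). Its annotated end lies 0.4 kb from Acss2, which rose by 1.68. The ferrochelatase Fech rose by 0.49. Of the NRF2 list, the ferritin light chain Ftl1 rose by 0.68, the heme transporter Slc48a1 by 0.62 and the biliverdin reductase Blvrb by 0.56. The call of Fech was lost in 5 of the 6 fits that left out 1 library (adjusted p from 0.109 to 0.198), that of Fcgr2b without any 1 control (0.0529 to 0.0675), and that of Ftl1 without control replicate 3 (0.0604). Ccr1, Gss, Slc48a1 and Blvrb kept theirs in those 6 fits.

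Gm14023 fell together with Il1a, which it overlaps on the other strand. Its RPKM was 17.3% to 20.51% of that of Il1a in each of the 6 libraries, and the log2 ratio had an SD of 0.09 and a difference of 0.09 between the groups. Both lie below the limit of 0.25 set for the test, so the values of Gm14023 are consistent with reads shared between overlapping genes. An antisense RNA made in proportion to Il1a would give the same ratio and was not tested.

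Genes that fell lay near each other on the chromosomes more often than random genes of like expression. Of the 72 lower genes, 17 pairs without overlap lay within 200 kb, against a median of 2, a 95th percentile of 4 and a highest value of 10 in 10000 random sets. The 153 higher genes also had an excess, with 16 pairs, more than in 98.3% of random sets (median 8, 95th percentile 14). The counts with families set aside, given next, cover the lower genes only. Without pairs inside a family and without Gm14023, 6 pairs were left, more than in 98.73% of random sets treated alike (median 2, 95th percentile 4), but these hold only 3 neighbours (Slc20a1, F830045P16Rik and Wfdc17), each paired with both members of Il1a and Il1b or of Ccl4 and Ccl9. With each tandem family counted as 1 gene 3 pairs were left, more than in 74.97% of random sets treated alike (median 2, 95th percentile 4), so tandem families and reads of Il1a counted for Gm14023 may account for the excess; regional control of unrelated neighbours was not tested further.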
